A study of Mus musculus with 2 samples.

How the data were processed

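Gene expression was measured in flushed whole bone marrow of C57Bl6 and C57Bl/KaLwRij mice with 1 Affymetrix mouse gene array per strain. Per the labels, each array carried total RNA pooled from 3 samples of its strain. The labels do not say how many animals stood behind the 3 samples, nor their age or sex. Per the labels' protocols, total RNA was isolated with Trizol and RNeasy, and 10 ng entered an isothermal amplification with NuGEN kits in 2 rounds that gave 16 to 19 µg of target, of which 83 to 84% was longer than the protocol's length criterion. Polyadenylated spike-in RNAs were added per the same protocol, and the target was fragmented and labelled with biotin.

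The values are log2 gene-level signals that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, sets the arrays to the same distribution by quantile normalisation and summarises the probes of each transcript cluster. A transcript cluster is the set of probes that the array assigns to a gene locus. Versions of the software and of the array design are not given in the sources used here. The Ensembl entries of the deposited annotation carry coordinates of mouse build NCBIM36. Quantile normalisation fixes the overall distribution of both arrays, so a shift common to most genes would not be visible in these values.

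The full deposited table held 35557 probe sets. Of these, 6559 were controls and 28998 were transcript clusters, of which 19757 had exactly 1 gene symbol, none had several and 9241 had none. Symbols were brought up to date through a RefSeq gene table of mouse assembly GRCm38.p6, which was used for names and gene order, not for coordinates. The match came from the accession for 16804 clusters, from the symbol for 1296 and from an unambiguous synonym for 676, and 981 clusters kept the name in the table. This gave 18187 genes. The deposited value table of the series was identical to the full table in every probe set, with 0 differences.

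The authors also deposited a column of log2 differences. Although its heading names C57Bl6 before C57Bl/KaLwRij, in every probe set it equals the C57Bl/KaLwRij value minus the C57Bl6 value. All differences given here run in that direction. A deposited summary table lists 32 clusters of the full table, and 2 further deposited tables come from a second RMA run of the same arrays. The other arrays of that run are not given in the sources used here, and only clusters with large differences were deposited from it. Over the 358 probe sets deposited, 288 of them controls, its levels lay lower than the full table's by a median difference of -1.21 log2 units in C57Bl6. It served as an alternative for named genes.

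With 1 array per strain there are 0 residual degrees of freedom. No test between strains was made, no p-value is given, and no difference has a replicate check. The number of arrays limits the precision, and a fold describes these 2 RNA pools. A cluster was counted when it differed at least 2-fold, had a gene symbol, and had its brighter array at or above 7.24, the median level of clusters with a gene symbol, which kept 10147 clusters. For a scale of the scatter between the arrays, clusters were placed in 20 bins of mean level, and the local deviation was 1.4826 times the median absolute deviation of the differences in the bin. This scale holds variation between genes as well as measurement error.

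There were 31 gene lists for cell types, pathways and sample handling. A gene entered with the mean of its clusters. Each list was summarised by the median difference of its measured members, and the percentile of that median among 10000 random lists of the same size, drawn from the same bins of level, describes where the list lies on these arrays. Medians at or below the 2.5th or at or above the 97.5th percentile are called outside the random lists. Genes of a list are not independent replicates. For independent genes in lists without shared members, 1.55 of 31 lists would lie outside by chance. Some of these lists share members, so that number is not a yardstick for them.

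Genes are named by a rule. It takes all measured members of the adiponectin axis and C57Bl/KaLwRij-associated lists, the 12 genes with the largest difference in each direction among the 10147 clusters, without clone-type and predicted names, and up to 4 members with the largest absolute difference in each list. A few genes that the rule takes are not reported here. Other genes named in the text lie outside the rule and were picked as examples with their values known. Gene families (histone, stefin, Gimap, receptor families and the clusters of Chd7) were grouped after the values were seen. The strain groups, the lists, the naming rule and the main alternatives were chosen before the data were examined.

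The alternatives were no filter on dim clusters, stricter filters, differences centred on the median, and removal of a loess trend on level (span 0.3). Further ones were thresholds of 1.5-fold and 3-fold, 1 value per gene and a threshold of 4 MAD. For the lists they were means in place of medians, bright members alone, and no shared genes. Added later were the second RMA run, members matched by the table's own symbol, and counts over all clusters but controls. The 2-fold threshold, without the level filter, and the list percentiles were tested on simulated data for the strain comparison with 18187 genes. Of 200 genes shifted by 1.5 log2 units, 100% were counted with the right sign, and 0 of 17987 unshifted genes were. The simulated scatter was normal, independent between genes and as wide as each bin's local deviation, so an unshifted gene could hardly reach 2-fold. It lacks the heavier tail of the negative controls, of which 53 of 2106 at or above the median level differed over 2-fold. Of 100 lists of 15 genes shifted by 0.2 log2 units, 99% lay above the 97.5th percentile, and 1% of 100 unshifted lists lay outside on either side. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.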

Results

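The C57Bl/KaLwRij strain, in which plasma cell tumours arise spontaneously with age and transplanted mouse myeloma lines grow, was compared with C57Bl6, in which those lines grow poorly. The comparison asks how the marrow of the permissive strain differs from that of C57Bl6. Each strain was represented by 1 array of flushed whole marrow RNA, pooled from 3 samples, so each value is a single measurement on the log2 RMA scale. Values ran from 2.83 to 13.7 in C57Bl6 and from 2.91 to 13.8 in C57Bl/KaLwRij, with medians of 6.98 and 7.003.

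The marrow of both strains was close to the same over most genes. Across the 19757 clusters with a gene symbol, Pearson's r between the arrays was 0.996 and Spearman's rho was 0.995, both taken across genes, which are not independent replicates. The median difference was 0.0027 and its SD 0.179 log2 units, and among clusters at or above the median level the median absolute difference was 0.104. The 9 hybridisation spike-ins differed by -0.15 to 0.09. The 4 polyadenylated spike-ins, which pass through the amplification, differed by -0.06 to 0.58. Of 2106 negative control probe sets at or above the median level, 53 (2.52%) differed over 2-fold, against 12 of 10147 clusters with a gene symbol (0.118%).

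A small set of genes stood far from this scatter. Gdpd3, a glycerophosphodiester phosphodiesterase, was 4.30 log2 units higher in C57Bl/KaLwRij, at 10.9 against 6.56 in C57Bl6. Negative control probe sets had a median of 6.59 in C57Bl6 and 6.58 in C57Bl/KaLwRij, so no fold is given for genes whose dimmer value lay near or below these. Samsn1, an adaptor that restrains B cell activation, was the lowest gene relative to C57Bl6, at 5.88 against 8.60, a difference of -2.72. Hpgd, the dehydrogenase that inactivates prostaglandins, was at 6.89 against 9.38, a difference of -2.49. Tnfrsf26, a member of the tumour necrosis factor receptor superfamily, was at 5.96 against 8.08, a difference of -2.12. Adipoq, which encodes adiponectin, was at 6.62 against 7.78, a difference of -1.17. Both Adipoq values lay between the 25th and 75th percentiles of the negative controls (5.29 to 7.82 in C57Bl6). Differences of negative controls at or above the median level had an SD of 0.41. In all, 3 clusters were at least 2-fold higher in C57Bl/KaLwRij and 9 were at least 2-fold lower. Gdpd3 lay 38.5 MAD from the median of clusters of like level, Samsn1 -26.3, Hpgd -22.1, Tnfrsf26 -20.6 and Adipoq -11.4. The count of lower clusters was 3 when both arrays had to reach the median level, since Samsn1, Hpgd, Tnfrsf26, Adipoq and both clusters of 2210012G02Rik (now Tceanc2) lay below it in C57Bl/KaLwRij.

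**Figure D1:**
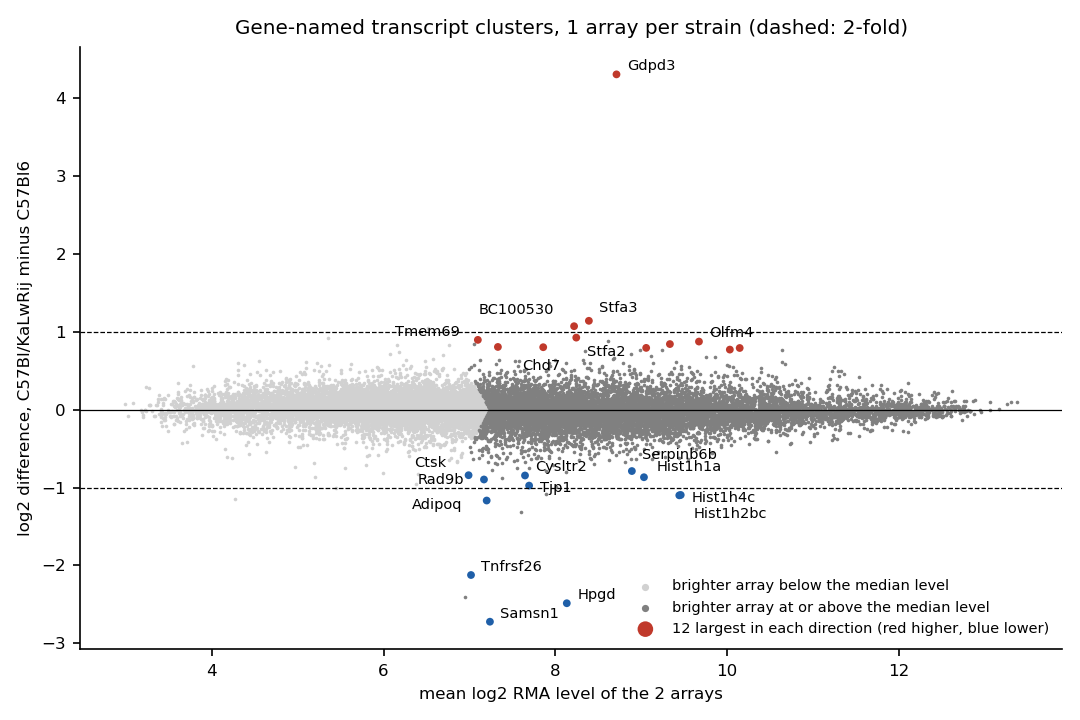
Log2 difference of each cluster with a gene symbol (C57Bl/KaLwRij minus C57Bl6, vertical axis) against the mean log2 RMA level of the 2 arrays (horizontal axis), 1 array per strain. Gdpd3 stands alone at 4.30, and Samsn1, Hpgd and Tnfrsf26 lie below -2, while the other labelled genes lie near the dashed 2-fold lines.

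After Gdpd3, the higher genes included several that myeloid cells express. The cysteine protease inhibitors Stfa3 (1.14), BC100530 (now Cstdc5, 1.07) and Stfa2 (0.92) led, and the 3 clusters at or above the median level whose symbol begins with Stfa were above 0, with a median of 0.92, and a dimmer Stfa2 cluster was at 0.47. Olfm4, a granule protein of neutrophils, was higher by 0.87, the formyl peptide receptor Fpr1 by 0.79, the signal regulatory protein Sirpb1 by 0.84 and Mrgpra2 by 0.77. The natural killer receptor family member Klra17 (0.80), Tmem69 (0.89), and Ptplad2 (now Hacd4, 0.79) were also among the 12. Chd7, a chromatin remodeller with many clusters on the array, was higher by 0.80 in its most different cluster, and all 28 of its clusters at or above the median level were above 0, with a median of 0.37.

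Among the lower genes, Hist1h4c (now H4c3) and Hist1h2bc (now H2bc4) both differed by -1.10, and Hist1h1a (now H1f1) by -0.87. Of 61 clusters of replication-dependent histone genes at or above the median level, 54 were below 0, but their median was -0.07, and with the loess trend removed 11 rather than 7 were above 0. Ctsk, the cathepsin of bone-resorbing osteoclasts, differed by -0.84, the tight junction gene Tjp1 by -0.98, the leukotriene receptor Cysltr2 by -0.85, Rad9b by -0.90 and Serpinb6b by -0.79. Outside the naming rule, and picked out after their values were seen, 2210012G02Rik differed by -2.41 and -1.31 in its 2 clusters, and 2310007D09Rik (now Fam83d) by -1.09.

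Adiponectin was of prior interest in this strain, and no gene of its pathway or of fat cells other than Adipoq reached 2-fold. In the adiponectin axis list, 6 of 9 genes were below 0, with a median of -0.11 at the 2.95th percentile of random lists. The receptors Adipor1 and Adipor2 differed by -0.15 and 0.0008, the binding partner Cdh13 by -0.16, the adaptor Appl1 by 0.14, the kinase subunits Prkaa1 and Prkaa2 by -0.14 and -0.11, and the nuclear receptors Ppara and Pparg by 0.17 and -0.01. The mean of the list, which takes in the full -1.17 of Adipoq, was -0.16 and lay at the 0.74th percentile, whereas the median was -0.072 (21.2nd percentile) over members at or above the median level and -0.059 (16.6th) without members shared with other lists. The 14 adipocyte markers had a median of 0.05, at the 79.1st percentile, and 8 were above 0. Beside Adipoq, the largest differences among them were Pck1 at 0.28, Lpl at -0.26 and Car3 at -0.25. Among the 6 adipocyte markers at or above the median level the median was -0.15, at the 2.54th percentile. Of the 5 C57Bl/KaLwRij-associated genes, 4 were below 0 and 3 at least 2-fold lower, with a median of -1.17. Beside Samsn1, Tnfrsf26 and Adipoq these were Tnfrsf22 (-0.20), with Nnt, which encodes a mitochondrial transhydrogenase, at 0.02. Those genes were listed because the strain was already known for them, Adipoq from work on this same comparison, so the list is not independent evidence of its direction.

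The list of marrow stroma genes was lower. Of 13 stromal markers, 9 were below 0, with a median of -0.16 at the 0.01st percentile of random lists. The leptin receptor gene Lepr, which marks perivascular stromal cells, differed by -0.81, the chemokine Cxcl12 by -0.79, Angpt1 by -0.64 and the stem cell factor gene Kitl by -0.33. Lepr (6.40 in C57Bl6) and Kitl (6.04) lay below the negative control medians in both arrays. The 4 members at or above the median level had a median of -0.36 at the 0.05th percentile. These were Cxcl12, Angpt1, Grem1 (-0.08) and Vcam1 (0.002), and all but Grem1 were in other lists too. Endothelial markers were below 0 in 8 of 12 genes, with a median of -0.11 (0.85th percentile). Vwf differed by -0.41, Pecam1 by -0.24, Eng by -0.18 and Emcn by -0.14, and the 4 members at or above the median level had a median of -0.21 at the 2.88th percentile. Vwf, 1 of those 4, is in the megakaryocyte and platelet list too, and without shared members the endothelial median was -0.09 at the 2.11th percentile. Emcn (5.31 in C57Bl6) lay below the negative control medians in both arrays.

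Bone cell genes differed in both directions. Of 14 osteoblast markers, 10 were below 0, with a median of -0.06 at the 6.06th percentile. The matrix genes Ibsp (-0.66) and Sparc (-0.47) were lower, and Bglap1 was higher by 0.36. The list mean, -0.13, lay at the 1.07th percentile, but the members at or above the median level had a median of -0.0022 at the 53.6th. The osteoclast list had a median of 0.07 at the 90.7th percentile, but several of its brighter members were lower. Ctsk differed by -0.84, Acp5, which encodes the tartrate-resistant phosphatase, by -0.50 and Atp6v0d2 by -0.46, while Mmp9, which neutrophils also express, was higher by 0.61. Among the 7 osteoclast markers at or above the median level the median was -0.38, below every random list. That median is the value of Itgb3, which is in the megakaryocyte and platelet list too. Without members shared with other lists, bright or dim, the osteoclast median was 0.07 at the 86.75th percentile.

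Of the myeloma niche cytokines and ligands, 13 of 21 were above 0, with a median of 0.11 at the 99.6th percentile. Inhba, the activin A subunit, was higher by 0.77. Il6, a growth factor of myeloma cells, was at 4.08 and 4.53, within the 3.79 to 4.97 of the Y-linked genes in these pools, so no direction is read from it. The members at or above the median level had a median of 0.09 at the 98.9th percentile. Tnf and Hgf were both higher by 0.27. Cxcl12 at -0.79 ran against the list.

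Neutrophil genes were higher throughout. All 17 measured neutrophil markers were above 0, with a median of 0.24 above all 10000 random lists. Mmp9 was higher by 0.61, the integrin gene Itgam by 0.48, the transcription factor gene Cebpe by 0.46 and Lcn2 by 0.43, while the abundant S100a8 and S100a9 were higher by 0.13 and 0.11. The eosinophil, basophil and mast cell list was above 0 in 13 of 14 genes, with a median of 0.14 at the 99.96th percentile. Its largest difference was Ccr3 at 0.36, followed by Prss34 at 0.22, Ear2 at 0.19 and Ear1 at 0.16. Monocyte and macrophage markers were split, 9 above and 9 below 0, with a median of -0.02 at the 53.5th percentile. The scavenger receptor Cd163 differed by -0.51, Mrc1 by -0.37, Ly6c2 by 0.23 and C1qa by -0.23.

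Genes of most other blood lineages were lower. Megakaryocyte and platelet markers had a median of -0.38, with 10 of 11 below 0, including Clec1b (-0.67), Itga2b (-0.48), Gp9 (-0.45) and Vwf (-0.41). Dendritic cell markers had a median of -0.29, with 11 of 12 below 0, including Clec9a (-0.62), Siglech (-0.51), Cd209a (-0.37) and Zbtb46 (-0.36). The erythroid median was -0.18, with Gata1 at -0.37, Epb42 at -0.32 and Alas2 at -0.29, whereas 3 of 14 genes, Hba-a1, Hbb-bt and Car1, were above 0. These 3 medians lay below all random lists. The T and NK cell median was -0.17 (0.07th percentile), with 14 of 17 genes below 0 and Klrd1 at -0.46, Lck at -0.31, Il2rb at -0.30 and Ncr1 at -0.29. Outside the lists, all 6 clusters of the lymphocyte GTPase family Gimap at or above the median level were below 0, with a median of -0.29.

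In the B lineage, mature B cell markers were below 0 in 12 of 14 genes, with a median of -0.25 at the 0.01st percentile. The complement receptor Cr2 differed by -0.53, Cd74 by -0.44 and H2-Aa by -0.33. Precursor markers had a median of -0.19 (0.06th percentile), with Il7r at -0.39, Vpreb3 at -0.34 and Ebf1 at -0.30. Bst1, which neutrophils also express, was higher by 0.71, and the surrogate light chain genes Vpreb1 and Vpreb2 by 0.20 and 0.22. The mean of that list, -0.082, lay at the 11.6th percentile. Plasma cell markers had a median of -0.12 at the 1.37th percentile, with Slamf7 at -0.45, Irf4 at -0.40, Jchain at -0.32 and Tnfrsf17 at -0.22. Its 8 members at or above the median level lay at the 6.81st percentile. The stem and progenitor list had a median of -0.06 (11.3rd percentile), with Slamf1 at -0.77, Angpt1 at -0.64, Ctnnal1 at -0.59 and Mllt3 at -0.42. Its 12 brighter members had a median of -0.20 at the 0.13th percentile.

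**Figure D2:**
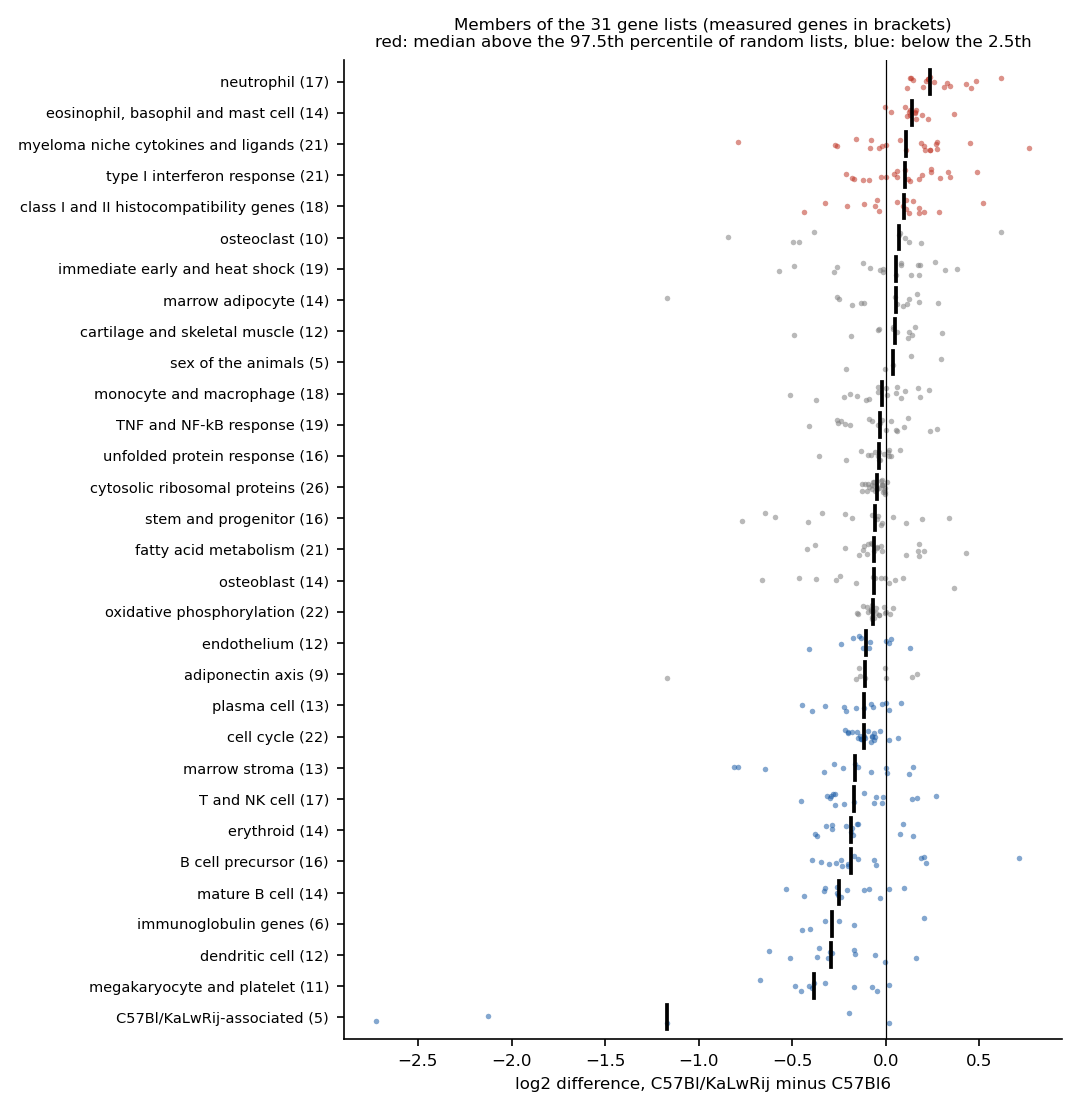
Log2 difference (C57Bl/KaLwRij minus C57Bl6, horizontal axis) of each measured member of the 31 gene lists, with a black bar at the list median and the number of genes in brackets, 1 array per strain. The neutrophil median is the highest at 0.24, and the C57Bl/KaLwRij-associated median of -1.17 and the megakaryocyte median of -0.38 are the lowest.

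The 6 measured immunoglobulin genes had a median of -0.29, below all random lists, and 5 were below 0, among them Igh at -0.45, Iglv1 at -0.41 and Jchain at -0.32. Most variable segments carry no gene symbol on the array. In a look made after the values were seen, short Ensembl transcripts without a symbol were collected from the kappa locus, on chromosome 6 from 67485214 to 70518356, and from the heavy chain locus, on chromosome 12 from 114101099 to 116448269, both in build NCBIM36. Of all 30 kappa clusters, 24 were below 0, with a median of -0.19. Of the 20 kappa clusters at or above the median level, 17 were below 0, with a median of -0.73, and 4 were at least 2-fold lower. The lowest of them, from 69610984 to 69611517 on chromosome 6, differed by -1.54, and the highest, from 68081463 to 68082197, by 0.65. The 11 heavy chain clusters at or above the median level had a median of -0.03, with 1 at -2.07, from 114710460 to 114710758 on chromosome 12. Outside this set, cluster 10403036, described as a heavy chain variable region and without coordinates in the table, differed by -1.96, and a heavy chain cluster below the level filter, from 116400346 to 116400639, by -1.04.

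**Figure D3:**
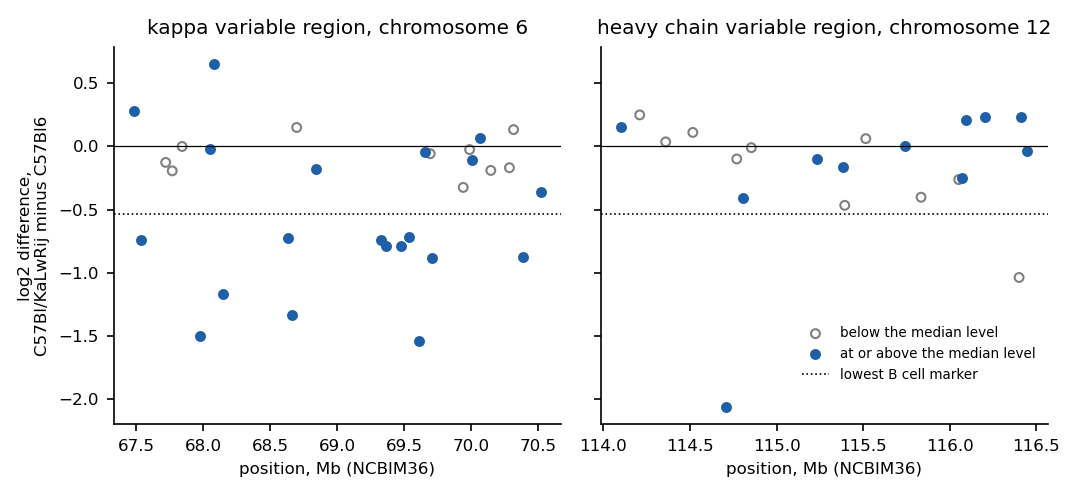
Log2 difference (C57Bl/KaLwRij minus C57Bl6, vertical axis) of transcript clusters in the kappa and heavy chain variable regions against their NCBIM36 position in Mb (horizontal axes), 1 array per strain. Kappa clusters spread from -1.54 to 0.65, most of them below 0, and the dotted line marks the lowest B cell marker at -0.53.

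The list of histocompatibility genes had a median of 0.10 at the 99.7th percentile, with 11 of 18 genes above 0, all of them class I genes or B2m, led by H2-Q10 at 0.52 and H2-Q1 at 0.29, while the class I gene H2-T22 was at -0.035. This split by class was made after the values were seen. The class II genes H2-Aa (-0.33), H2-Eb1 (-0.21) and H2-Ab1 (-0.12) and the invariant chain Cd74 (-0.44) were below 0. The list mean, 0.042, lay at the 92.8th percentile. Type I interferon response genes were above 0 in 15 of 21 cases, with a median of 0.10 at the 99.8th percentile, including Ifi27l2a at 0.48, Oasl2 at 0.34 and Oas1a at 0.33, while Ifit2 differed by -0.21.

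Cell cycle genes were lower by small amounts, with 20 of 22 below 0 and a median of -0.12 at the 0.22nd percentile. Mcm2 (-0.22), Mcm5 and Mcm7 (-0.20 each) and Mcm3 (-0.18) led. The remaining lists lay inside the random lists. Ribosomal protein genes had a median of -0.05 (8.24th percentile), oxidative phosphorylation genes -0.07 (4.13th), fatty acid metabolism genes -0.06 (13.9th), unfolded protein response genes -0.04 (40.0th) and TNF and NF-kB response genes -0.03 (23.7th). In fatty acid metabolism, Dgat1 was higher by 0.43 and Scd1 differed by -0.42 and Scd2 by -0.38. Herpud1 differed by -0.36 and Cxcl2 by -0.41. Immediate early and heat shock genes, which respond to tissue handling, had a median of 0.06 (94.2nd percentile) with Jun at -0.57 and Fos at -0.49 against Ier3 at 0.38 and Atf3 at 0.31. Cartilage and skeletal muscle genes had a median of 0.05 (74.3rd percentile), with Mylpf at -0.49 and Acta1 at 0.30. Xist, the transcript of the inactive X chromosome, was at 11.3 in both strains, and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty lay at 3.79 to 4.97. These Y-linked values lay below the 25th percentile of the negative controls (5.29 in C57Bl6, 5.23 in C57Bl/KaLwRij). Both pools therefore had the pattern of female marrow, and the sex genes did not separate them.

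The 32 clusters of the authors' deposited table were all the clusters other than controls that differed by over 1 log2 unit, 10 higher and 22 lower in C57Bl/KaLwRij. Of these, 15 had a gene symbol. Clusters below the level filter in that table included Lyrm7 at 1.04 and Mc2r at -1.01. The authors' deposited table of their second RMA run held 70 clusters over 1 log2 unit, 31 higher and 39 lower, all 70 with the same sign as in the full table, and 27 of the 32 were among them. Both runs used these arrays, and clusters with smaller differences in the second run could not appear, so the shared sign is no independent check. In that deposited table the difference was 5.03 for Gdpd3, -2.77 for Samsn1, -2.34 for Hpgd and for Tnfrsf26, and -1.06 for Adipoq. Other named genes lay further from their values in the full table, with Cysltr2 at -1.58 against -0.85, Hist1h4c at -1.67 against -1.10 and BC100530 at 1.56 against 1.07.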

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

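The clusters in this part were picked after their values were seen. They have no gene symbol, so the strain comparison did not count them, and each was over 1 log2 unit higher in C57Bl/KaLwRij than in C57Bl6. The largest, transcript cluster 10582545, has no annotation in the deposited table and differed by 1.38 log2 units. A cluster for a cloned RNA binding site of the Dazl protein differed by 1.28. An Ensembl small nucleolar RNA on chromosome 10, from 9542209 to 9542339 in build NCBIM36, differed by 1.15. The transcript of 9530008L14Rik, known to the table as an Ensembl entry without a symbol, differed by 1.06, and so did cluster 10525914, which has no annotation. A Genscan prediction on chromosome 19, from 34684811 to 34686028 in the same build, differed by 1.03. The cluster of 1.38, that of the Dazl binding site and cluster 10525914 lay below the level filter of 7.24 in both arrays. Among negative control probe sets at or above the median level, 53 of 2106 differed over 2-fold, a share that does not cover the dimmer clusters. Clusters without a symbol that were lower by over 1 log2 unit are not part of this set. Among them, the transcript of 4930503L19Rik differed by -1.35 and an Ensembl transcript on chromosome 9, from 8555792 to 8556019, by -1.01. No explanation was tested for any of these clusters.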

How the results depend on the processing

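Chosen after seeing the data were the second RMA run, members matched by the table's own symbol, and counts over all clusters but controls. No paired analysis was possible because each strain has 1 array, and no replicate could be left out. The series' value table, identical to the full table, moved nothing. The counts of 3 higher and 9 lower clusters stayed within 1.5 times without the level filter (4 and 11), centred (3 and 10), with the loess trend removed (3 and 9) and per gene (3 and 8). They were 39 and 61 at 1.5-fold, 1 and 4 at 3-fold, and 226 and 184 over 4 MAD. Over all clusters but controls, with the level filter kept, they were 6 and 19. With both arrays at or above the median level, or the brighter at or above the 75th percentile, 3 lower clusters were left, since fewer clusters enter. Of the 17 lists outside the random lists, 13 stayed outside on the same side under all alternatives run. The exceptions were, with bright members alone, endothelium (-0.21, 2.88th percentile) and plasma cell (-0.12, 6.81st), and by the mean, B cell precursor (-0.082, 11.6th) and histocompatibility genes (0.042, 92.8th). Of the 14 lists inside, 10 stayed inside under all alternatives run, and adiponectin axis, osteoblast, osteoclast and stem and progenitor did not. Bright members alone gave -0.15 for adipocyte, -0.0022 for osteoblast, -0.38 for osteoclast, 0.12 for cartilage and muscle, -0.20 for stem and progenitor and -0.016 for immediate early genes. The mean gave -0.16 for the adiponectin axis, -0.075 for adipocyte, -0.13 for osteoblast, -0.10 for osteoclast, -0.17 for stem and progenitor and -0.0018 for immediate early genes. The table's own symbols gave -0.036 for adipocyte and -0.11 for osteoblast. Where the value is from bright members, fewer genes enter, and otherwise the cause was not tested. In the second run, 4 named genes moved by less than the local deviation and 10 by more, with no change of direction. Only clusters over 1 log2 unit in that run were available, so named genes with smaller differences there could not appear. Signal limits dim genes such as Il6, whose levels of 4.08 and 4.53 lie below the median level of 7.24.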

Other observations

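Further gene families were grouped after their values were seen, over clusters at or above the median level. All 6 clusters of the paired receptor genes Pilra, Pilrb1, Pilrb2 and Sirpb1 were higher in C57Bl/KaLwRij, with a median of 0.66 log2 units and a range of 0.60 to 0.84. Among Fc receptor genes, Fcgr4 was higher by 0.59 and Fcgr3 by 0.36, with Fcgr1 at -0.15. Among Toll-like receptor genes, 6 of 9 were above 0, led by Tlr6 at 0.64 and Tlr13 at 0.42, and Tlr12 differed by -0.20. The Schlafen genes Slfn4 (0.58), Slfn1 (0.49) and Slfn2 (0.40) were higher, with 6 of 8 above 0. Clec genes were split 5 above and 6 below 0, Clec5a at 0.58 and Clec4b2 at 0.51 against Clec1b at -0.67 and Clec9a at -0.62. With the loess trend removed, 7 Schlafen genes and 6 Clec genes were above 0. A cluster without a symbol, described in the deposited table as Erdr1, differed by -1.10 at levels of 11.2 and 10.1.

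Of the tests that follow, the loess test of the neutrophil genes and the share of lower clusters in the tail were set down before their results were seen, and the others were chosen after.

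The neutrophil list was higher while lymphoid, dendritic and megakaryocyte lists were lower. The values argue against a trend of the difference with signal level, since the loess trend moved no cluster with a gene symbol by more than 0.04. The neutrophil median was 0.26 after the loess trend was removed and 0.24 before. With a trend this small, the fall set down in advance as the mark could not occur, so the size of the trend is what speaks here. A gain of neutrophils that diluted all other cells alike would put the eosinophil, basophil and mast cell list below 0, but its lower quartile was 0.12. A different balance of granulocytic and other lineages in the C57Bl/KaLwRij pool, or different expression per cell, may underlie the pattern. Differences between animals, dissection or flushing are confounded with strain in 1 pool each and stay open.

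Of the genes that differed 2-fold, those outside the stefin and histone families were Gdpd3, Samsn1, Hpgd, Tnfrsf26, Adipoq and, under clone-type names, 2210012G02Rik (-2.41 and -1.31) and 2310007D09Rik (-1.09). A strain variant under probes designed on C57Bl6 sequence would lower the C57Bl/KaLwRij signal, which the 4.30 of Gdpd3 goes against, but for the lower genes it stays open. Of 364 clusters outside the lists that lay over 4 MAD out, 43.1% were lower (exact 95% interval 37.98 to 48.4). This lay below the even share set in advance as the mark against variants. That mark was wrong, since the share also depends on the higher side, where 13 clusters were of Chd7 alone. With 1 value per gene 45.1% were lower (39.7 to 50.5), and at 1.5-fold 58.1% of 86 clusters (47.0 to 68.7). At 2-fold 66.7% of 9 clusters were lower (29.9 to 92.5). All of these intervals treat clusters of 1 pool per strain as independent. A gain or loss of a segment with several genes would move the neighbours. The 28 nearest measured neighbours of these 7 genes had a median of 0.14 towards the gene, an upper quartile of 0.21 and a highest value of 0.50. Of them, 18 were at or above the median level, with a median of 0.18 and an upper quartile of 0.28, and the dimmer ones could hardly show a loss. As a set these neighbours moved little, but values pooled over 7 genes cannot decide for any single gene. Beside Hpgd all neighbours lay towards it, with Fbxo8 at 0.44. Neighbours of Stfa3, BC100530, Hist1h4c and Hist1h2bc, many of them members of the same families, had a median of 0.46, which leaves a segment change open there. A change at each gene itself, in regulation, sequence or copy, could give isolated differences, and was not tested.

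In the collected set of immunoglobulin variable-region clusters, 12 of 20 kappa clusters and 1 of 11 heavy chain clusters lay below the lowest of 30 B cell markers, Cr2 at -0.53. Fewer B-lineage cells would lower the clusters about as much as B cell markers, and 60.0% of the kappa clusters (exact 95% interval 36.1 to 80.9) fell further than every marker. That share was scored on the values that prompted the look, and its interval treats clusters of 1 pool as independent. The markers come from the precursor and mature B cell lists, without the plasma cell list. Fewer cells of some B-lineage stage therefore stays open for kappa, and the heavy chain share of 9.09% (0.230 to 41.3) leaves it open too. Strain variants in the segments stay open, because the SD of 0.597 among the kappa and 0.653 among the heavy chain differences, against 0.195 among other clusters, restates the spread that prompted the look. Different use of segments by the B cells of each pool stays open as well.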
